A study of Arabidopsis thaliana with 12 samples.

How the data were processed

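Total RNA was taken from leaves of Arabidopsis thaliana, wild type (accession Col-0) and the cs26 mutant, a SALK line of the locus AT3G03630. The series title describes its product as an S-sulfocysteine synthase needed for chloroplast function. Plants grew on soil either in long days (16 h of light and 8 h of dark) or in short days (8 h of light and 16 h of dark), at 20 °C in the light and 18 °C in the dark. Long-day plants were 3 weeks old and short-day plants 5 weeks old at harvest, so photoperiod and age changed together. Each of the 4 groups has 3 arrays, which the design text calls biological replicates. Per the labels' protocols, RNA was isolated with Trizol and cleaned on a column, and biotin-labelled cRNA was made from 4 µg of it and hybridised to Affymetrix ATH1 arrays, 1 array per sample. The number of arrays limits the precision of every value.

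The deposited values are on a log2 scale with 2 decimals and run from 3.12 to 14.27. The submitters' processing notes name RMA, which corrects background, quantile-normalises the arrays and summarises the probes of each probe set, and the affy package. Their versions, and whether all 12 arrays were normalised in a single run, are not given in the sources used here. Array medians lay between 5.42 and 5.51. RMA sets the distributions of the arrays alike, so a shift shared by most transcripts would be removed from these values. It also leaves dim probe sets near the background, where differences are compressed. Scanner files are not used here.

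The table holds 22810 probe sets on 12 arrays with 0 missing values. The 64 Affymetrix control probe sets were left out of all tests, which leaves 22746. In the platform annotation used, 13513 of these name 1 gene (13356 genes), 503 name several and 8730 are unnamed. Symbols were updated by gene number to the TAIR10.1 gene table, which held 13436 of the 13513. That table served only for names and for which genes neighbour each other. Probe sets with several genes or none stayed in the tests and are not named. Many well-studied genes, CS26 itself included, have no probe set here that names them alone, so their values are not analysed by gene. Unnamed probe sets were called more often than those naming 1 gene, in long days 29.1% against 21.7% and in short days 20.1% against 14.7%.

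Groups were taken from the genotype and photoperiod in the labels. All 12 arrays entered 1 linear model with a mean per group, fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 8 residual and 4.32 prior degrees of freedom. The contrasts were cs26 against wild type in long days, the same in short days, the difference of those effects (short days minus long days), and short against long days in wild type. P-values were adjusted by Benjamini-Hochberg over the 22746 probe sets, and a probe set was called at an adjusted p under 0.05, with no limit on fold change. Adjusted p in the text comes from this limma model unless a gene list test is named, and errors of fold changes are the model's standard errors (SE).

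Named genes followed a rule set before the data were examined. For each cs26 comparison these are the 12 largest rises and the 12 largest falls among called probe sets that name 1 gene and whose values do not overlap between the groups. For wild type the number is 8 of each. For the difference it is the 10 largest, with no overlap between the genotypes in either photoperiod. Up to 4 members of each gene list are added to these.

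Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, which compares a list's genes with all other genes, using for each gene its brightest probe set. Before the data were examined, 24 lists were fixed for photosynthesis, chlorophyll and plastid function, sulfur and glucosinolate metabolism, redox, stress, hormone, senescence, starch and clock genes, and other leaf cell types. Of the 436 members these lists give by locus, 70 had a probe set naming that gene alone. The plastid genome list was a rule and held 69 genes. The rule was written for a form of locus identifier that the gene table does not use, and it was read as genes on the plastid chromosome after the files were seen. Benjamini-Hochberg adjustment ran over the 18 fixed lists with at least 2 measured members. Because so few members were measured, 4 lists (cytosolic ribosome; heat shock proteins and co-chaperones; photosystem, NDH and thylakoid assembly; immune signalling and defence proteins) and 30 symbol families of at least 8 genes were added from the annotation after its gaps had been seen and before any expression value of their members was looked at. They were adjusted together, apart from the fixed lists. Each list was tested again with camera's estimated correlation and with fry, which asks whether a list's genes move 1 way on balance and compares them with no other genes. Of the 47 list calls, the adjusted p with an estimated correlation was the highest over all settings tried for 42, and that without probe sets below the median brightness for the other 5. The immune list shares members with the salicylate, jasmonate and senescence lists, so their results are not independent. The same holds for the RPS family, whose genes are all in the plastid genome list.

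Alternatives set beforehand were quantile normalisation and median centring of the values, leaving out dim probe sets, fitting only the compared arrays, a replicate block, a trended robust prior, array weights, stricter thresholds, leaving out probe sets that can hit several genes, and leaving out each array in turn. The model was tested on simulated arrays with each probe set's real mean over all arrays and real spread, and independent noise. In these, 200 of the 22746 probe sets were changed. Far more were called in the real data (24.61% in long days and 16.73% in short days). The shares below therefore describe the simulated setting and need not hold for the real comparisons. In the simulated long-day comparison, 59.7% of probe sets changed 1.5-fold, 86.6% of those changed 2-fold and 100% of those changed 4-fold were recovered. For short days these shares were 55.2%, 97% and 100%. For the difference of effects they were 32.8%, 82.1% and 97%. False calls made up 3.5%, 3.4% and 4.7% of calls, in that order. In the simulated wild-type comparison 61.2%, 92.5% and 98.5% were recovered and 8.7% of calls were false. Camera was checked on 50 simulated unchanged lists of each of 2 sizes in the long-day comparison over 13356 genes. It gave p under 0.05 for 4 lists of 4 genes and for 0 lists of 30 genes, and for 49 and 50 after a shift of 0.3 (log2). The simulated genes varied independently, so this check does not cover lists whose genes are correlated. The estimated correlation was 0.432 for the plastid genome list and 0.105 for the cytosolic ribosome list. With estimated correlations 40 of the 47 list calls were lost.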

Results

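Leaf transcripts of wild type and of the cs26 mutant were measured in long days and in short days, with 3 arrays in each of the 4 groups. The study set out to find the genes that differ between mutant and wild type in each photoperiod. CS26, the mutated gene, has no probe set that names it alone in the annotation used here, so the labels could not be checked by its level. Over the 2000 most variable probe sets, the first principal component (69% of the variance) separated long-day from short-day arrays. The second (23%) separated the genotypes, but in opposite order. In long days wild-type arrays lay from -29.8 to -27.94 and cs26 arrays from 28.95 to 31.56, whereas in short days wild type lay from 11.81 to 12.8 and cs26 from -17.22 to -11.48. Replicate 2 of cs26 in short days varied most around its group mean (SD over probe sets 0.208, against 0.104 to 0.155 on the other arrays). Among the control probe sets, the 25S ribosomal RNA probe set read 9.64 on replicate 2 of wild type in long days and 4.53 to 5.12 on the other 11 arrays.

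In long days, the chitinase gene CHI and the calmodulin-like gene CML41 were among the largest rises in cs26 leaves, and the cold-responsive genes COR15A and COR15B were the largest named falls. CHI (AT2G43570) rose by 4.22 ± 0.17 (log2, SE, n = 3 arrays per group), 18.6-fold (adjusted p = 2.77e-09). CML41 rose 24.3-fold (4.60 ± 0.148). COR15A, a cold-induced chloroplast protein, fell by 5.40 ± 0.19, from a mean of 12.32 in wild type to 6.91 in cs26 (adjusted p = 8.23e-10), and its close relative COR15B fell by 4.90 ± 0.101. The starch enzyme APL3 (a large subunit of ADP-glucose pyrophosphorylase) fell by 2.99 ± 0.175 and the sugar transporter SWEET13 fell by 3.06 ± 0.131.

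The other named rises in long days were AT2G18690 (4.62 on the log2 scale), AT3G01830 (4.51), AT3G47480 (4.21), AT2G33850 (4.05), plastid rbcL (3.94 ± 0.415), which encodes the large subunit of Rubisco, BGLU25 (3.82 ± 0.166), AT5G52760 (3.71), AT3G18250 (3.68), AT5G39670 (3.67) and AT1G57630 (3.60). The other named falls were TBL26 (-3.58), AT1G80130 (-3.58), AT1G78070 (-3.38), AT5G22460 (-3.12), plastid psbB (-2.86 ± 0.488), AT4G33490 (-2.79), AT1G22160 (-2.78) and AT1G15410 (-2.75). BGLU25 encodes a member of the beta-glucosidase family and is the gene next to CS26.

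All 4 measured genes of the cold, drought and abscisic acid list fell in long days, with a median of -3.61 (camera adjusted p = 6.78e-08; adjusted p = 0.0135 with an estimated correlation). COR47 (-2.33) and LTI30 (-0.95), both dehydrins, fell beside the COR15 pair. The 4 measured phenylpropanoid and anthocyanin genes also fell, with a median of -1.76 (adjusted p = 8.14e-05; adjusted p = 0.0349 with an estimated correlation), among them DFR (-2.13), AT4G14090 (-1.82) and UF3GT (-1.70), all of anthocyanin synthesis. The 3 starch genes fell, with a median of -1.17 (adjusted p = 0.00136; adjusted p = 0.0349 with an estimated correlation), with PWD, a kinase of starch breakdown, at -1.17 and DPE1 at -0.76. The 3 oxidative stress genes rose, with a median of 0.55 and the transcription factor STZ (ZAT10) at 3.06 (adjusted p = 0.00136; adjusted p = 0.0349 with an estimated correlation). Of 3 senescence genes 2 rose, WRKY53 by 2.48 and WRKY6 by 1.36 (adjusted p = 0.00585; adjusted p = 0.0607 with an estimated correlation). Of 2 salicylate and systemic resistance genes, GRX480 rose by 2.55 and SAG101 measured 0.50 (adjusted p = 0.0104; adjusted p = 0.0607 with an estimated correlation). Adjusted over the list alone, both salicylate genes rose. The salicylate call was also lost with probe sets below the median brightness left out (0.0531).

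Among 69 genes encoded in the plastid genome, 6 rose and 19 fell in long days (20 fell adjusted over the list alone), with a median of -0.39 (camera adjusted p = 5.87e-04; adjusted p = 0.462 with an estimated correlation). Falls included psbB, psbJ (-1.87) and psbE (-1.77), which encode photosystem II proteins, and ribosomal protein genes such as rpl36 (-2.62). Plastid genes varied more between replicates, with a median residual SD of 0.394 against 0.134 for the other 13287 genes.

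Of 66 measured genes of the cytosolic ribosome list 63 rose in long days (64 adjusted over the list alone), with a median of 0.61 and AT2G19740 at 1.29 (adjusted p = 2.54e-30; adjusted p = 0.0214 with an estimated correlation). Of 29 immune signalling and defence genes, 18 rose and 3 fell (20 and 3 adjusted over the list alone), with a median of 0.73 (adjusted p = 8.94e-10; adjusted p = 0.0968 with an estimated correlation). PDF1.2, a defensin induced by jasmonate, rose by 2.88, OSM34 by 2.0 and the kinase gene BIK1 by 1.17, whereas MYC4 fell by 1.5. The 34 photosystem, NDH and thylakoid assembly genes (2 rose and 8 fell, adjusted p = 0.501) and the 9 heat shock genes (2 rose, adjusted p = 0.839) were not called as lists.

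The other 11 fixed lists tested were not called in long days (camera adjusted p from 0.0881 to 0.518). Of 3 glucosinolate genes 2 fell, BCAT4 by 0.31 and AT2G31790 by 0.44. Of 3 sulfate and cysteine synthesis genes, APS3 fell by 0.36 and APS4 by 0.30, both ATP sulfurylases. Of 8 tetrapyrrole genes 4 rose and PORB, a protochlorophyllide oxidoreductase, fell by 1.04. LHCB4.2 fell by 1.32 and was the only 1 of 6 photosystem II genes called, and limma called neither of the 2 photosystem I genes (1 at an unadjusted p under 0.05). Of 4 photorespiration genes 2 fell. SPCH, a stomatal lineage factor, rose by 0.36, and TRY, a trichome repressor, fell by 0.48, among 4 epidermal genes (2 rose and 1 fell adjusted over the list alone). TRXF2 rose by 0.44 among 6 thioredoxin system genes, and AT2G43030 rose by 0.27 among 3 genes of plastid translation. Of 3 Calvin cycle genes limma called 0 (1 at an unadjusted p under 0.05), and of 5 antioxidant genes also 0 (3 unadjusted). Lists with a single measured gene had no list test: the clock gene GI fell by 1.05 (adjusted p = 0.00392), AUR1, a marker of dividing cells, measured 0.38 (adjusted p = 0.055, called adjusted over the list alone), the vascular SWEET11 measured -0.06, and PDF1.2 alone stood for jasmonate. The sulfur starvation and flowering lists had 0 measured members. For the fixed lists of this comparison not given with a second count, adjustment over the list alone gave the same number.

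In all, 5597 of 22746 probe sets were called in long days, 2908 higher and 2689 lower in cs26, and 1303 of them changed at least 2-fold (723 higher and 580 lower). The higher genes were fewer than the lower ones with probe sets below the median brightness left out (2362 and 2380), with array weights (3308 and 3387) and without replicate 1 of cs26 (2597 and 2664). Over all 22746 probe sets, the 3 values of cs26 and of wild type did not overlap in 38.2%, where chance gives 10%. Without replicate 2 of wild type, the array with the high 25S signal, 4667 were called. The Bacillus control transcripts averaged 7.1 in wild type (7.04 to 7.18) and 6.6 in cs26 (6.48 to 6.69) in long days, without overlap. A part of array processing in the long-day comparison is therefore not excluded and was not tested.

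In short days, plastid rbcL and accD, the defensin gene PDF1.2 and BGLU25 were higher in cs26, and the chitinase gene CHI, SAL2 and UGT76B1 were lower. rbcL rose by 5.87 ± 0.415 (58.5-fold, adjusted p = 1.7e-06, n = 3 arrays per group), from 7.50 ± 0.21 (SD) in wild type to 13.37 ± 0.66 in cs26. The accD gene, for a subunit of plastid acetyl-CoA carboxylase, rose by 4.50 ± 0.518, PDF1.2 by 3.58 ± 0.15 and BGLU25 by 3.32 ± 0.166. CHI fell by 3.93 ± 0.17 (adjusted p = 2.55e-08), from 11.16 to 7.23. SAL2 fell by 2.98 ± 0.16 and UGT76B1, a glucosyltransferase that acts on defence signals, fell by 2.61 ± 0.151.

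The other named rises in short days were rpl20 (2.64), PDF1.2b (2.49), AT1G53540 (2.37), AT5G51440 (2.12), psaI (1.98), rps15 (1.90), AT5G12110 (1.88) and ycf3 (1.72 ± 0.441). The PDF1.2b probe set is of a kind that can also bind related transcripts such as PDF1.2. The ycf3 call (adjusted p = 0.0181, from 0.00109 to 0.0705 over the settings tried) was lost without replicate 1 (0.0691) or 2 (0.0624) of wild type or replicate 3 of cs26 (0.0503), with only the short-day arrays (0.0705) and with a trended robust prior (0.0501), and without replicate 2 of cs26 its rise was 1.14. The other named falls were AT2G44240 (-2.95), AMY1 (-2.87), an alpha-amylase, AT3G13610 (-2.38), AT1G05575 (-2.36), AT5G52390 (-2.34), AT5G39670 (-2.28), AT3G01830 (-2.28), AT1G72060 (-2.27) and AT1G57630 (-2.23).

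Of 34 photosystem, NDH and thylakoid assembly genes 15 rose in short days (18 rose and 1 fell adjusted over the list alone), with a median of 0.30 (camera adjusted p = 1.17e-07; adjusted p = 0.00461 with an estimated correlation). CRR21, an editing factor for NDH transcripts, rose by 1.11, CYTC6A by 0.94, SPPA by 0.89 and LIL3:1 by 0.66. Of 29 immune genes 3 rose and 14 fell (4 and 17 adjusted over the list alone), with a median of -0.37 (adjusted p = 4.95e-06; adjusted p = 0.327 with an estimated correlation), with UGT76B1, CML41 (-2.08) and WRKY53 (-2.02) among the falls and both defensin genes among the rises. Of 9 heat shock genes 5 rose, with a median of 0.48 and the small heat shock protein gene AT1G53540 highest (adjusted p = 3.42e-04; adjusted p = 0.403 with an estimated correlation). Of 66 genes of the cytosolic ribosome list 7 rose (3 adjusted over the list alone), with a median of 0.10 (adjusted p = 0.0224; adjusted p = 0.645 with an estimated correlation). That call was lost without replicate 1 or 3 of cs26 or replicate 1 or 3 of wild type (adjusted p from 0.0524 to 0.122), with quantile normalisation (0.12), with fry (0.0836) and with probe sets below the median brightness left out (0.294).

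Among the fixed lists, 4 of 5 antioxidant genes rose in short days (5 adjusted over the list alone), with a median of 0.42 (adjusted p = 0.00854; adjusted p = 0.132 with an estimated correlation), among them GR, the plastid glutathione reductase, at 0.56 and SAPX at 0.45. Of 4 photorespiration genes 2 rose (3 adjusted over the list alone), AT1G80380 by 0.51 and HPR by 0.33 (adjusted p = 0.0239; adjusted p = 0.147 with an estimated correlation). Of 2 salicylate and systemic resistance genes, GRX480 fell by 1.57 (both fell adjusted over the list alone; adjusted p = 0.0219; adjusted p = 0.143 with an estimated correlation). Of 3 senescence genes WRKY53 and WRKY6 (-0.32) fell (adjusted p = 0.0298; adjusted p = 0.147 with an estimated correlation, and 0.0502 without replicate 1 of wild type). Of 69 plastid genes 14 rose and 6 fell, the same numbers adjusted over the list alone, and the list was not called (adjusted p = 0.0684). The lowest adjusted p among the other 13 fixed lists was also 0.0684, for the Calvin cycle, where 1 of 3 genes rose (3 adjusted over the list alone). With probe sets below the median brightness left out, camera called none of the antioxidant (0.0863), photorespiration (0.254), senescence (0.0521) and salicylate (0.0522) lists. Adjustment over the list alone gave further calls in other lists not called, among them starch (2 of 3 rose, against 1), plastid translation (2 of 3, against 1), tetrapyrrole (4 of 8, against 2), and sulfate and cysteine synthesis (1 rose and 1 fell, against 0 by limma). GI (0.52) and SWEET11 (0.22) were higher by that adjustment only, and 1 more glucosinolate gene rose. The phenylpropanoid and anthocyanin list had a median of -0.05 and a mean of 0.088, and camera's direction was upward (adjusted p = 0.656).

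In all, 3806 probe sets were called in short days, 2022 higher and 1784 lower in cs26, and 473 changed at least 2-fold (150 higher and 323 lower). The balance of all calls turned with quantile normalisation (1782 higher and 1954 lower), at an adjusted p under 0.01 (960 and 1027), and without replicate 1 of wild type (1271 and 1362) or replicate 3 of cs26 (1448 and 1481). Over all 22746 probe sets, the values of the groups did not overlap in 29.8%, where chance gives 10%. Without replicate 2 of cs26, the array that stood apart, 3210 were called.

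**Figure D1:**
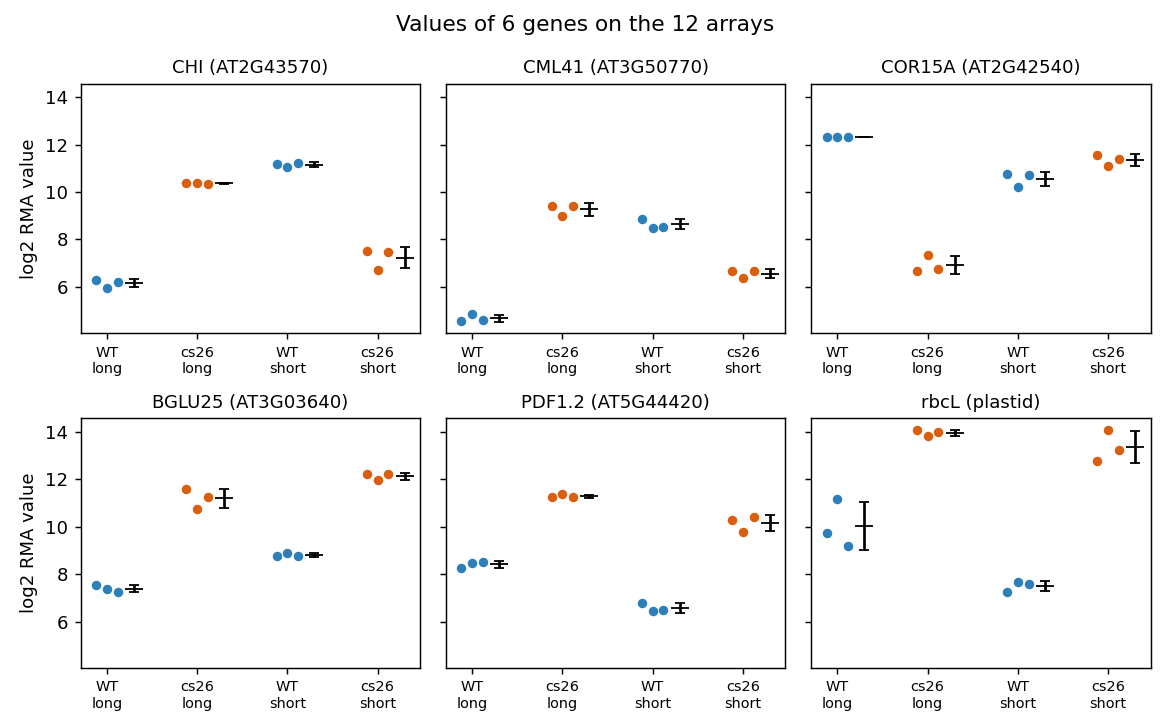
Log2 RMA values of CHI, CML41, COR15A, BGLU25, PDF1.2 and rbcL on the 12 arrays, with 3 points per group (blue wild type, orange cs26) and the mean ± SD beside them. CHI means were 6.15 and 10.37 in long days (wild type, cs26) and 11.16 and 7.23 in short days, whereas BGLU25 was higher in cs26 in both photoperiods (7.38 against 11.20 and 8.82 against 12.14).

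The effect of cs26 differed between the photoperiods for many of these genes, and often turned its direction. CHI was higher in cs26 in long days and lower in short days, a difference of effects of -8.15 ± 0.241 (log2, adjusted p = 1.74e-10). The same order held for CML41 (-6.68), AT3G01830 (-6.79), AT2G18690 (-6.53), SAL2 (-6.53), AT3G47480 (-6.00), AT5G39670 (-5.95) and AT2G44240 (-5.89). COR15A (6.20 ± 0.269) and COR15B (5.87) went the other way, lower in cs26 in long days and higher in short days (0.80 and 0.98 there). In total the effect differed for 6268 probe sets, with 3370 higher and 2898 lower in short days than in long days.

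Of the 42 genes named in the long-day or short-day comparison, 23 were called in opposite directions and 9 in the same direction in both. Over all probe sets, 1949 were called in both comparisons, 1544 in opposite and 405 in the same direction (268 without replicate 1 of wild type in short days). The number higher in long days and lower in short days was 976 (228.1 for independent lists), and 568 went the reverse way (239). Higher in both were 260 (258.5 for independent lists) and lower in both 145 (210.9). The log2 fold changes of the comparisons, which share no array, had a Pearson r of -0.424 and a Spearman rho of -0.315 across probe sets, which are not independent replicates.

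**Figure D2:**
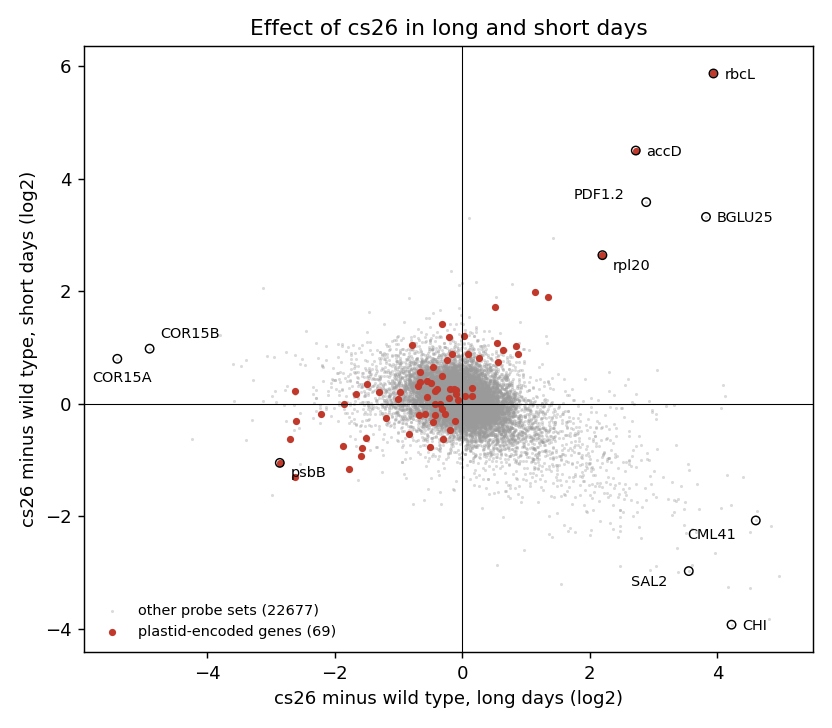
Log2 fold change of cs26 against wild type in long days (x axis) and short days (y axis) for 22746 probe sets, with the 69 plastid genes in red and named genes ringed. The cloud runs from upper left to lower right (Pearson r = -0.424), with CHI and CML41 at lower right, COR15A and COR15B at upper left, and rbcL, accD, BGLU25 and PDF1.2 at upper right.

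rbcL, BGLU25, PDF1.2, accD, PDF1.2b and rpl20 had the largest rises shared by both photoperiods, by the smaller of the effects, among probe sets with 1 gene and no overlap between groups, a selection made after the values were seen. PDF1.2 rose by 2.88 in long days and 3.58 in short days. The difference of effects was called for PDF1.2 (0.70, adjusted p = 0.0271) and for rbcL (1.93, adjusted p = 0.0271). Values of rbcL in cs26 reached 14.09 in both photoperiods, close to the array maxima of 14.18 to 14.27, so a limit of the scale on its fold changes and on their difference is not excluded. The difference of effects was not called for BGLU25 (-0.50 ± 0.235, adjusted p = 0.143), accD (1.78, adjusted p = 0.0947), PDF1.2b (-0.41, adjusted p = 0.355) and rpl20 (0.44, adjusted p = 0.407). Among the 69 plastid genes, 12 were called in both photoperiods, 6 higher and 6 lower in cs26, all in the same direction in long and short days. Their effects followed in part the order of the genes on the plastid chromosome, as judged after the values were seen. rbcL, accD, psaI and petA, which lie close together, were called higher in both (ycf4 and cemA, between psaI and petA, were not), and psbJ, psbL, psbF and psbE, which follow, were called lower in both. So were the adjacent rpoA and rpl36. By contrast, rpl20 and rps15 were called higher in both beside rps18 and ndhH, which were called in neither. Over the 69 genes the long-day and short-day effects had a Pearson r of 0.822 and a Spearman rho of 0.668 across genes. Their medians lay on opposite sides of 0 (-0.39 in long days and 0.21 in short days).

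**Figure D3:**
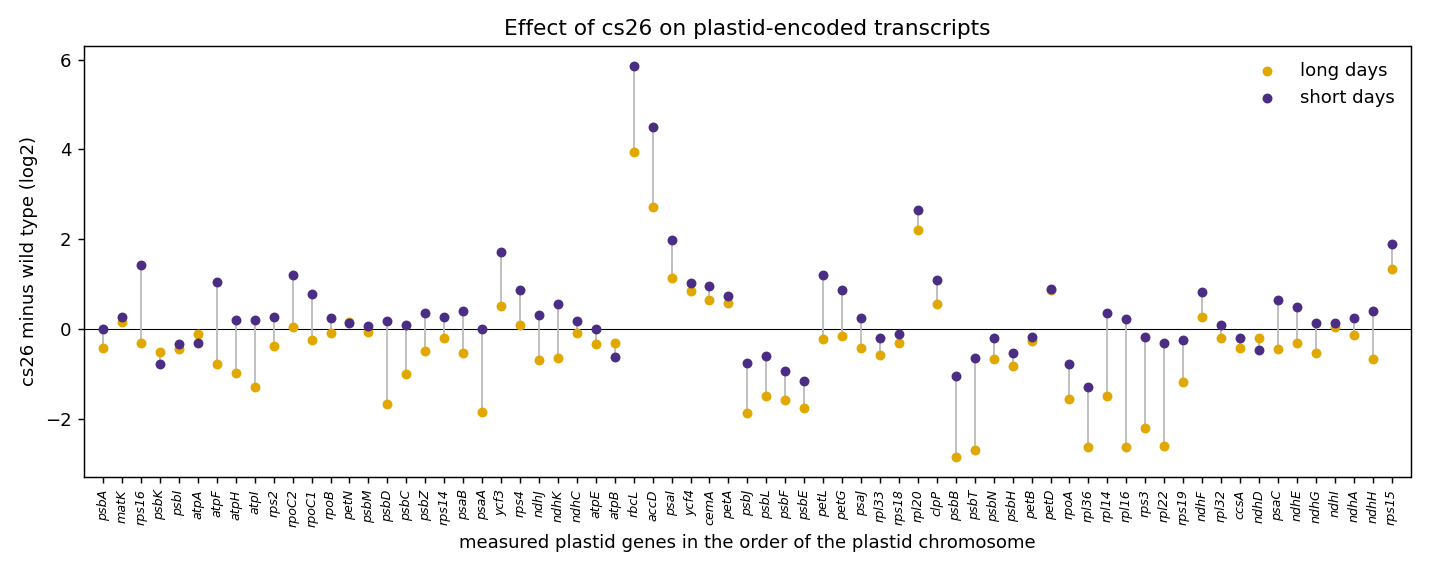
Log2 fold change of cs26 against wild type for the 69 measured plastid genes, in chromosome order (x axis), in long days (yellow) and short days (purple), with a grey line joining the 2 values of a gene. rbcL reaches 3.94 and 5.87, and psbJ to psbE lie below 0 in both photoperiods.

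The difference of effects was called for 9 of the 18 fixed lists tested. With an estimated correlation camera called 0 (7 at an unadjusted p under 0.05). The largest median difference was that of the cold, drought and abscisic acid list (4.1, adjusted p = 1.96e-05; adjusted p = 0.0511 with an estimated correlation), where 3 of 4 genes were higher. The salicylate and systemic resistance (-2.58), starch (2.0), phenylpropanoid and anthocyanin (1.71), senescence (-1.68) and oxidative stress (-0.52) lists were also called, but each had an adjusted p = 0.0565 with an estimated correlation. The antioxidant list had a median difference of 0.70 (adjusted p = 0.0956 with an estimated correlation), photorespiration 0.62 (adjusted p = 0.141) and the plastid genes 0.67 (adjusted p = 0.4, the last 2 also with an estimated correlation), with 20 of 69 plastid genes higher. The photorespiration call was lost without replicate 1 of cs26 (0.0538) or replicate 3 of wild type (0.0516) in short days. With probe sets below the median brightness left out, antioxidant (0.192), oxidative stress (0.075) and photorespiration (0.204) were not called. In these 9 lists, adjustment over the list alone gave the same counts. Median, mean and test differed in sign for 4 lists far from the threshold (adjusted p = 0.992): epidermal, plastid translation, thioredoxin and tetrapyrrole genes. Of the added lists, cytosolic ribosome (-0.52, 43 of 66 lower, 48 adjusted over the list alone) and immune genes (-0.94, 21 of 29 lower) were called, but had an adjusted p = 0.0633 with an estimated correlation, and the thylakoid assembly list (0.37, 14 of 34 higher and 1 lower) kept its call (adjusted p = 0.0299). Heat shock genes were not called (adjusted p = 0.0836).

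The wild-type arrays compare short-day with long-day plants, which differed in photoperiod and age, without the mutation. AT5G48490 was 76.3-fold higher in short-day than in long-day wild type (6.25 ± 0.195, adjusted p = 9.76e-11, n = 3 arrays per group). ORA47, a jasmonate-responsive transcription factor, was 43.9-fold higher (5.46 ± 0.161) and CHI 32.2-fold higher (5.01 ± 0.17). AT1G07050 fell by 6.08 ± 0.129. COR27, a cold- and clock-regulated gene, fell by 4.80 ± 0.103, and PWD fell by 4.2 ± 0.271. The other named rises were AT1G13650 (5.80), AT3G10930 (5.6), AT4G29780 (5.41), AT2G20670 (5.10) and AT2G24550 (5.08), and the other falls AT4G30650 (-4.88), AT4G16146 (-4.86), AT5G39410 (-4.60), AT1G31690 (-4.52) and plastid psaA (-4.25 ± 0.551).

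The 3 starch genes were lower in short-day wild type, with a median of -3.24 (adjusted p = 0.00544; adjusted p = 0.124 with an estimated correlation), and so were 3 of 4 phenylpropanoid and anthocyanin genes, with DFR at -3.87 (adjusted p = 0.00644; adjusted p = 0.169 with an estimated correlation). Of the cold, drought and abscisic acid list 3 genes fell and LTI30 rose by 0.50 (adjusted p = 0.0326; adjusted p = 0.169 with an estimated correlation). Both salicylate and systemic resistance genes rose (adjusted p = 0.0437; adjusted p = 0.169 with an estimated correlation), a call lost without replicate 1 (0.0674) or 3 (0.0627) of short days or replicate 2 of long days (0.0634). Of 69 plastid genes 11 rose and 28 fell (12 and 31 adjusted over the list alone; adjusted p = 0.0426; adjusted p = 0.727 with an estimated correlation), a call lost without the same 3 arrays (0.115, 0.198 and 0.135), with quantile normalisation (0.0954) and with fry (0.163). Adjustment over the list alone left the numbers of the starch, phenylpropanoid, cold and salicylate lists as they were. Of the added lists, 43 of 66 genes of the cytosolic ribosome list rose (45 adjusted over the list alone; adjusted p = 1.11e-08; adjusted p = 0.33 with an estimated correlation) and 17 of 29 immune genes rose and 5 fell (adjusted p = 0.00743; adjusted p = 0.43). Of 9 heat shock genes 3 rose (adjusted p = 0.0392; adjusted p = 0.43), a call lost without replicate 2 of short days (0.0544) or of long days (0.0548). Of 34 thylakoid assembly genes 2 rose and 13 fell (adjusted p = 0.0446; adjusted p = 0.33), a call lost without replicate 2 of long days (0.0777) and with quantile normalisation (0.096). The second p of these last 3 lists is that with an estimated correlation. With probe sets below the median brightness left out, the starch and phenylpropanoid lists alone were called among the fixed ones (adjusted p = 0.118 for the other 3), and the immune (0.201), thylakoid assembly (0.201) and heat shock (0.136) calls were lost. The 13 other fixed lists were not called (adjusted p from 0.197). Of 3 Calvin cycle genes 1 fell (2 adjusted over the list alone), and the photosystem II genes had a median of 0.04 and a mean of -0.057 (adjusted p = 0.755).

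In wild type 10186 probe sets were called, 4949 higher and 5237 lower in short days, and 2683 changed at least 2-fold. Control probe sets differed between the photoperiods too, which was not tested. The 3' minus 5' signal of the actin control was 1.14 ± 0.2 (SD) in long-day and 2.08 ± 0.35 in short-day wild type, with cs26 at 1.14 and 2.07. The same signal moved by 0.45 in wild type for the GAPDH control and by 0.05 for ubiquitin. The Bacillus control transcripts averaged 7.1 in long-day and 5.68 in short-day wild type, whereas the E. coli and phage control transcripts averaged 9.55 and 10.14. Age differed with photoperiod, and so did these control signals. The comparison therefore holds photoperiod, age and any difference in the RNA or the processing of the arrays, which cannot be told apart. The hour of harvest is not given in the labels.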

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

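The tests of exchanged labels, of harvest time, of the genes around CS26, of the BGLU family and of the plastid genes were chosen after the results had been seen.

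The results below stand out because the effect of cs26 differed between long and short days, by the test of the difference itself. This held for 6268 probe sets and for 34 of the 42 genes named in the long-day or short-day comparison. Among probe sets that name 1 gene and whose genotypes do not overlap in either photoperiod, the largest differences (short-day minus long-day effect, log2) were those of CHI (-8.15), AT3G01830 (-6.79), CML41 (-6.68), AT2G18690 (-6.53), SAL2 (-6.53), COR15A (6.20), AT3G47480 (-6.00), AT5G39670 (-5.95), AT2G44240 (-5.89) and COR15B (5.87). Among gene lists, the median difference was 4.1 for cold, drought and abscisic acid genes, 2.0 for starch, 1.71 for phenylpropanoid and anthocyanin, 0.70 for antioxidant, 0.67 for plastid genome and 0.62 for photorespiration genes. It was -2.58 for salicylate, -1.68 for senescence and -0.52 for oxidative stress genes. Among added lists it was 0.37 for thylakoid assembly, -0.94 for immune and -0.52 for cytosolic ribosome genes. Of these lists, only thylakoid assembly kept its call with an estimated correlation (adjusted p = 0.0299).

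The first pattern is that most genes called in both photoperiods went opposite ways. An array that stands apart does not account for it: with each array left out in turn, the correlation of the long-day and short-day effects stayed at or below -0.398. Exchanged cs26 and wild-type labels in 1 photoperiod are argued against, though not excluded without CS26 itself, by BGLU25 (higher in cs26 in both, the smaller effect 3.32) and by the 12 plastid genes called in both photoperiods, all in the same direction. Across the 69 plastid genes the long-day and short-day effects had a Pearson r of 0.822 and a Spearman rho of 0.668. Harvest at different times of the day stays open: of the clock list only 1 gene was measured, GI (-1.05 in long days and, not called, 0.52 in short days). Clock-regulated COR27, looked up afterwards, measured 0.06 in long days and -0.03 in short days and was called in neither. Its short-day means (4.19 in wild type and 4.16 in cs26) lay near the lower end of the scale. Its short-day value therefore says little on harvest time. The test of the difference shows that the measured effect of cs26 was not the same in long-day and short-day plants (6268 probe sets). Whether this goes with photoperiod or with age, which changed together, stays open. A part of array processing is not excluded either. A control difference between photoperiods that both genotypes share would cancel in this test. Between the genotypes, the Bacillus controls differed by -0.49 in long days and 0.25 in short days (cs26 minus wild type). The E. coli and phage controls differed by -0.32 and -0.07, and the 3' minus 5' signals by -0.15 to 0.08. These control differences were not tested.

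The second pattern is BGLU25, the gene next to CS26, which was higher in cs26 by 3.82 in long days and by 3.32 in short days. A change of the whole chromosome region is argued against by the 9 other measured genes within 12 places on either side, which went both ways and far less: from -0.517 to 0.507 in long days (median 0.153, with 3 called) and from -0.393 to 0.173 in short days (median -0.03). On the BGLU25 side of CS26 only AT3G03670 and AT3G03680, at places 4 and 5, were measured besides BGLU25. EDA5 and WOX11, directly beyond BGLU25, were not, so a change confined to that side is hardly tested. A rise of the whole BGLU family is argued against too, since limma called 0 of the 19 other members higher in both photoperiods (also 0 at an unadjusted p under 0.05). An effect of the insertion on the adjacent gene and a response of BGLU25 alone to the loss of CS26 both stay open as hypotheses and were not tested.

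The third pattern is the block-wise change of plastid-encoded transcripts, called higher in both photoperiods at rbcL, accD, psaI and petA and lower at psbJ, psbL, psbF and psbE. The adjacent rpoA and rpl36 were also called lower in both. Not every change lay in a block: rpl20 and rps15 were called higher in both, beside rps18 and ndhH, which were called in neither. Uneven labelling of plastid RNA as a class is argued against as the only cause, because the called plastid genes went both ways. At least 24% of them went the less frequent way in each photoperiod. A class-wide shift on top of changes of single genes is not excluded. Labelling that differs from gene to gene could also go both ways, so this test cannot see it. It was not tested and is not excluded, also for the large rises of rbcL and accD. Of the called plastid genes, 24% were higher in long days and 70% in short days. The difference of effects was called higher for 20 of 69 plastid genes and lower for 0. A single array does not carry the agreement of long-day and short-day effects over the plastid genes, as their correlation stayed at 0.788 or more with each array left out. This does not bear on the blocks, because the correlation of adjacent genes was not recomputed with arrays left out. Effects of adjacent plastid genes correlated at 0.468 (permutation p = 0.0001 over 100000 shuffled orders, 1-sided), in line with neighbouring genes changing together. That may reflect shared transcripts, a hypothesis found and tested on the same data, and whether their transcription or processing differs was not tested.

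For the difference of effects, 1 of 100 drawn splits of genotypes within photoperiods, the real one, called as many as 6268 probe sets. The highest of the others called 3671. With the labels exchanged in short days only, 3547 were called. Splits of this kind give calls also where only 1 photoperiod has a genotype effect. The rank of the real split therefore speaks only against no genotype effect at all. It cannot decide whether the effects of the photoperiods differ by chance. All 9 drawn splits that part the long-day arrays by their real genotypes, the real one included, had calls. Of the other 91, 6 had calls, at most 102, and these 6 part the short-day arrays by their real genotypes, so the calls follow the genotypes in each photoperiod. For long days, short days and wild type, the 3 against 3 arrays give only 10 splits, too few for a share under 0.05. The real split alone, 1 of 10 in each, called as many as 5597, 3806 and 10186 probe sets, and the highest other called 0.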

How the results depend on the processing

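No named gene or called list reversed its direction, and no probe set called in the model of all 12 arrays changed sign under an alternative that tested it. The balance of calls did turn under some: with quantile normalisation 1782 were higher and 1954 lower in short days, and with dim probe sets below the median left out 2362 and 2380 in long days. Quantile normalisation, median centring, array weights, a trended robust prior, fitting only the compared arrays, the milder filter on dim probe sets and leaving out probe sets that can hit several genes kept the numbers of probe sets called within 1.5 times. Quantile normalisation ended 3 list calls: cytosolic ribosome in short days (0.12), and plastid genome (0.0954) and thylakoid assembly (0.096) in wild type. Named genes kept their call in 798 of the checks with other settings and lost it in 3, all of them ycf3 in short days. With arrays left out they kept it in 501 and lost it in 3, again ycf3. Named genes had been chosen as the largest called changes without overlap between groups, so few losses were likely beforehand. Lists kept theirs in 262 and lost it in 67, and with arrays left out in 349 and 23.

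Counts moved with stricter thresholds, by construction. With an added 2-fold limit they were 1303 (long days), 473 (short days), 2503 (difference), 2683 (wild type), 262 shared calls and 17 in the same direction. At an adjusted p under 0.01 they were 1987 for short days, 4057 for the difference, 985 shared and 154 in the same direction, with 3850 and 7244 for long days and wild type. Among the 18 fixed lists tested, camera called 7, 4, 9 and 5 in the same order of comparisons, 4, 0, 0 and 0 with an estimated correlation (6, 4, 7 and 4 at an unadjusted p under 0.05), and fry called 17, 12, 14 and 13. With dim probe sets below the median left out, 0 were called in short days and 2 in wild type, although the medians of the antioxidant (0.42), photorespiration (0.34) and salicylate (-1.06) lists in short days were the same. For this filter, the estimated correlation and fry the cause was not tested.

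With each array left out, counts ran from 4636 to 5261 in long days, 2633 to 3756 in short days, 5352 to 6305 for the difference and 8484 to 9570 in wild type. Shared calls ran from 1447 to 1888, and those in the same direction from 268 to 425. Fixed lists called were 7 to 7 in long days, 3 to 5 in short days, 8 to 10 for the difference and 3 to 5 in wild type. Added lists and families varied too. In long days 1 family was called without replicate 1 of wild type and 4 without its replicate 3, against 3 with all arrays. The low of 268 came without replicate 1 of wild type in short days, and the 3 fixed lists in wild type without that array, replicate 3 of short days or replicate 2 of long days.

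The replicate numbers do not pair the arrays. Of 18 same-numbered pairs across groups 2 had correlated deviations over 0.1 (range -0.31 to 0.162), and 1 of 12 arrays correlated best with its own number. With the replicate block the counts were 5216, 3297, 5770 and 9654, with 1695 shared calls and 343 in the same direction, and the numbers of fixed lists called were 7, 4, 9 and 5. For the difference, fitting only the compared arrays is the same model as the fit of all 12. CS26 could not be followed under any setting. Signal over background is not given in the values used here, so differences of dim probe sets may be understated, and lists of 2 to 6 genes, as in the 4 of 18 kept in long days, rest on few members.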

Other observations

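Beside the plastid genes, defensins and BGLU25, a few nuclear genes, chosen after their values were seen, changed in the same direction in both photoperiods. EXLB1, an expansin-like gene, fell by 1.63 ± 0.189 (log2, SE, n = 3 arrays per group) in long days and by 1.36 in short days. AT3G51870 rose by 1.32 ± 0.087 and 1.2, AT1G57770 by 0.89 and 1.07, and AT3G51750 by 1.05 and 0.96. AT1G04040 measured -0.95 and -1.04, lower in cs26 in both.

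Among 30 symbol families, camera called 3 in long days, 1 in short days, 3 for the difference and 2 in wild type. With an estimated correlation camera called 0 (3, 0, 2 and 2 in that order at an unadjusted p under 0.05). Of 8 ALDH genes (aldehyde dehydrogenases) 4 fell in long days, with a median of -0.37 (adjusted p = 0.00861; adjusted p = 0.245 with an estimated correlation), among them ALDH7B4 (-1.15) and ALDH3F1 (-0.88). The IQD family had 7 falls and 1 rise among 15 genes (adjusted p = 0.0276; adjusted p = 0.245 with an estimated correlation) and the TRM family 5 falls among 15 (adjusted p = 0.0338; adjusted p = 0.245 with an estimated correlation). With probe sets below the median brightness left out, the ALDH (0.0664), IQD (0.0661) and TRM (0.285) calls were lost. Without replicate 1 of wild type the IQD and TRM calls were lost (0.0573 each), and without replicate 2 of cs26 the TRM call (0.0776). In short days 5 of 8 ATG genes, of autophagy, fell (adjusted p = 4.6e-04; adjusted p = 0.531 with an estimated correlation), with ATG8E at -1.19. In long days ATG8E rose by 1.39, a difference of effects of -2.58. The families called for the difference were ALDH, IQD and RPS (camera adjusted p = 0.0172, 0.0173 and 0.0262). The 8 RPS genes are the plastid rps genes, all members of the plastid genome list, so the RPS call is not a separate result. The RPS call was lost without replicate 2 of cs26 (0.0971) or replicate 1 (0.0557) or 3 (0.0589) of wild type in short days. Those called in wild type were IQD and UBP, and UBP was lost without replicate 2 of long days (0.0512). With probe sets below the median brightness left out, of these calls only IQD for the difference was kept.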
